A study of Homo sapiens with 4 samples.

How the data were processed

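The samples were 4 single-cell RNA-seq libraries of 1 group, mock-infected lymphoblastoid cell lines, made with the 10x Chromium 3' version 3.1 chemistry per the labels' protocols. Lymphoblastoid lines are B cells made immortal in culture with Epstein-Barr virus. Each cell was drawn from a pool of 384 lines. Cell Ranger 7.0.1, Seurat and the GRCh38 build are named in the submitters' processing notes, which give no role for each. The cell filters, the removal of doublets and the way cells were assigned to lines are not given in the sources used here, and whether each library held all 384 lines is not stated.

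The authors deposited raw UMI counts (unique transcript counts) for 36601 genes in the cells of 4 libraries, and a second table of counts per gene summed per line. Each cell name begins with the library name that the labels give, and the libraries were taken from it. Over all 36601 genes, the per-line table held 99.9963% of the UMIs in the cell matrix, and 8389 genes had a different total in the 2 tables. On reading, 111 genes were then dropped, all genes of the Y chromosome with XIST and TSIX, which took 0.078% of the counts. By name, 33873 genes were matched to GENCODE release 29 on GRCh38, and coordinates are from that annotation, 1-based. Gene annotation of the authors is not given in the sources used here. The title of the series names sex-biased expression. Because no label or file states the sex of a line, that comparison was not analysed here.

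Total UMIs were 270652964, 566309288, 464270496 and 424425554 in replicates 1 to 4. Total counts per line had a median of 3751810, with a 5th percentile of 1070314 and a 95th percentile of 11064195. All 384 lines had at least 100000 counts and 380 had at least 500000. No file or label states a sequencing batch. Only summaries over lines were computed, and no line is named.

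With 1 group in the labels, comparisons were made inside the pool. Lists of genes were fixed for 18 cell states and 6 other cell types, and these lists, the tests, the alternatives and the rule for named genes were set before the data were examined. For each cell, UMIs were drawn down to 3500, the 10th percentile of UMIs per cell rounded down to a multiple of 500. This left out 4829 shallower cells (637, 1269, 1206 and 1717 in replicates 1 to 4) and kept 49415. The UMIs of a list in the thinned cell were its score. Within each library, cells above the 75th percentile of a score formed the high range and cells at or below the 25th percentile the low range. A range is not a cell type. The unthinned counts of each range were summed per library, which gave 8 sums per score. The quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) compared high with low sums after TMM normalization and the default expression filter, with library as a block, since both ranges came from the same library. Members of the score's own list were left out. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with a log2 difference of at least 0.5 in size. The SE of a log2 difference was taken from its quasi-likelihood F statistic. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes.

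Across lines, a score was the mean over list members of z-scored log2 CPM with a prior count of 2, scaled to an SD of 1. The edgeR test of its slope had log10 of the line total as a covariate and covered genes with a mean CPM of at least 5. A gene was called at an adjusted p under 0.05 with a slope of at least 0.2 log2 units per SD. Correlations between list scores were Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples, adjusted over 153 pairs. The smallest p these permutations can give is 1e-05. The coefficient of variation of a gene between lines was the square root of edgeR's tagwise dispersion, with log10 of the line total as a covariate. It was taken for genes with a mean CPM of at least 10. The kappa share was IGKC over IGKC plus the lambda constant genes, in cells with at least 10 such UMIs and in lines with at least 100. Isotype shares in cells were taken over cells with at least 10 and lines with at least 100 heavy chain constant UMIs, where the plan named light chain UMIs. A share of 0.9 or more was called kappa and of 0.1 or less lambda. Binomial intervals are exact Clopper-Pearson intervals at 95%, a 0 allows up to 3 counts, and both cover counting error only.

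Named genes were, for each cell comparison, the 10 largest rises and 10 largest falls among called genes that moved the same way in all 4 libraries with a mean CPM of at least 10, and up to 3 called members of each list. For lines they were the 10 largest positive and 10 largest negative slopes with a mean CPM of at least 10 and up to 3 called members of each list. For variation they were the 20 largest coefficients. Immunoglobulin and T cell receptor V, D and J segments, mitochondrial and ribosomal protein genes were given only as groups, and clone-named and LINC loci were left out. Constant genes of the immunoglobulin loci and the HLA genes have near-identical copies, so their counts can be split between members. Reads were not checked for strand, and antisense genes are uncertain.

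No doublet caller was run. An alternative left out the 6991 cells over 2 times the median UMIs of their library, and another the 2109 cells with over 10% mitochondrial UMIs. Other alternatives changed the size factors, the filter, the tool (DESeq2 1.42.0 or limma voom), the score, its percentiles, the thinning depth and the block, limited cells to low cycle scores, or left out each replicate in turn. For lines they changed the size factors, the mean CPM minimum, the score, the covariates, the minimum total and the tool.

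The edgeR tests of cells and lines and the score correlations were run on simulated data with known answers. In the edgeR runs 100 genes per effect size were changed. Camera with the preset correlation was run only on a simulated list of mostly raised genes, with genes drawn independently. Its false calls and its results for correlated genes were not tested. Camera with an estimated correlation, fry and Dixon's test were not run on simulated data. In cells, log2 differences of 0.5 and 1 were recovered for 66% and 88% of genes with the NF-kB score (21214 genes), 59% and 84% with the plasmablast score (20880 genes), 72% and 93% with the interferon score (20667 genes) and 61% and 91% with the G2/M score (20415 genes). Unchanged genes made up 3.14%, 4.67%, 9.34% and 7.32% of the calls. In these runs, of cells and of lines, a gene was recovered at an adjusted p under 0.05 with the right sign. The size threshold of a call was not applied, so these shares are not those of the full call rule. In lines, slopes of 0.2 were recovered for 95%, 98%, 96% and 86% of genes in the same order of scores, and slopes of 0.4 for 100%. Unchanged genes made up 2.99%, 5.71%, 2.97% and 7% of those calls (10790, 10798, 10786 and 10765 genes). Of 50 simulated pairs with r of 0.2, 98% were called, as were 2% of 100 pairs with r of 0. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for thinning, scores, permutations and plots.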

Results

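The transcripts of single cells from a pool of 384 lymphoblastoid cell lines, B cells immortalised by Epstein-Barr virus, were counted in 4 mock-infected libraries. Replicates 1 to 4 held 9316, 16508, 13368 and 15052 cells, with a median of 27114.5, 32022, 31899 and 24763 UMIs and 6097.5, 6473, 6432 and 5722.5 genes per cell. Mitochondrial genes took a median of 4.44% to 4.60% of the UMIs of a cell. At least 3 T cell markers were found in 211 cells, or 0.382% ± 0.0452 (SD, n = 4), and at least 3 epithelial markers in 22 cells. The T cell markers TRAC and TRBC2 had a mean of at least 10 CPM over the lines, with coefficients of variation of 0.241 and 0.511. Cells with 3 T cell markers therefore need not be T cells. NK cell markers reached this number in 2 cells and myeloid markers in 1. Erythroid and fibroblast markers reached it in 0 cells of the 4 libraries, which allows a share of up to 0.00553%.

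The levels of the cell state lists differed little between libraries. The NF-kB target list, genes induced by a transcription factor that the viral protein LMP1 activates, stood at 3779 ± 97.8 CPM (SD, n = 4). Plasmablast genes, markers of antibody-secreting B cells, stood at 2678 ± 28.8 CPM, G2/M phase genes at 5861 ± 114 CPM and p53 targets at 1049 ± 3.57 CPM. The interferon response list had the widest relative spread of the 18 state lists, 3390 ± 216 CPM, a coefficient of variation of 6.37% against a median of 1.77% over the state lists. Of the other cell types, T cell markers summed to 53.8 ± 0.887 CPM, epithelial to 8.75 ± 0.662, NK to 3.70 ± 0.129, myeloid to 2.73 ± 0.224, fibroblast to 1.32 ± 0.0488 and erythroid to 0.411 ± 0.0736 CPM. The T cell sum includes TRAC and TRBC2, so it does not measure the share of T cells.

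The labels give 1 group, so the first question was which genes changed together with 4 states inside the pool. Cells with a high score were compared with cells with a low score within each library. Values are log2 differences, high minus low, with the SE over 4 libraries, and each named leading gene moved the same way in 4 of 4 libraries. The p-values measure only the spread between these 4 libraries, which may be technical. High and low cells come from different lines in unknown proportions, so a difference can lie between lines, between cells of a line, or both.

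Cells with many NF-kB target transcripts expressed more immediate early and MHC class II genes and fewer antibody genes than cells with few. XKR4, a member of the XK family of membrane proteins (chromosome 8, 55102389 to 55542054, GRCh38), was higher by 6.18 ± 0.12, from 0.351 to 27.8 CPM. MMP7, a matrix metalloproteinase, was higher by 5.50 ± 0.11, and IL2RA, the alpha chain of the interleukin-2 receptor (chromosome 10, 6010689 to 6062370), by 4.80 ± 0.05, from 1.28 to 35.0 CPM. JCHAIN, which joins IgA and IgM into polymers (chromosome 4, 70655541 to 70681817), fell by 3.26 ± 0.02, from 877 to 90.6 CPM. ZBP1, a sensor of Z-form nucleic acids, fell by 3.21 ± 0.04, and IGHA1, the constant region of IgA1, by 2.77 ± 0.02. The other leading rises were ENOX1 (4.52), the somatostatin receptor SSTR2 (4.16), RASSF4 (4.01), NOL4L (4.00), KIF26B (3.74), the chemokine gene CCL4L2 (3.70) and brain-type creatine kinase CKB (3.69). CCL4L2 is a CCL4-like gene and CCL4 is a member of the NF-kB list, so its rise may not be independent of the score. Leading falls included IGLC1 (-2.86), IGLC2 (-2.56), IGLC3 (-2.45), IGHG2 (-2.40), the protein disulfide isomerase TXNDC5 (-2.34), IGHGP (-2.33) and LAX1 (-2.32).

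Of 14 immediate early genes, which respond to signals without new protein synthesis, 12 rose and 0 fell, with EGR2 at 2.26 ± 0.05, ATF3 at 2.19 ± 0.04 and DUSP2 at 2.13 ± 0.04 (camera adjusted p = 1.06e-07, and adjusted p = 0.186 with an estimated correlation). Of 13 MHC class II genes 8 rose, among them the master regulator CIITA by 1.38 ± 0.04 (adjusted p = 1.06e-07, and adjusted p = 0.289 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 19 cases, led by INSIG1 (1.55 ± 0.03) and LSS (1.12 ± 0.03; adjusted p = 3.11e-07, and adjusted p = 0.286 with an estimated correlation). Among 21 p53 targets 8 rose, including the death receptor FAS (1.32 ± 0.03), and 1, TP53INP1, fell by 1.53 ± 0.04. Immunoglobulin constant genes fell in 12 of 14 cases and V, D and J segments in 101 of 107, while IGHE, at a mean of 1.88 CPM, rose by 1.03 ± 0.16. The plasmablast list fell in 14 of 20 genes, with DERL3 at -2.47 ± 0.05, and SLAMF7 rose by 1.03 ± 0.02 (adjusted p = 2.08e-11, and adjusted p = 0.186 with an estimated correlation). Of 54 G2/M genes 40 fell, led by PSRC1 (-1.56 ± 0.13) and CDC20 (-1.31 ± 0.04), and of 42 S phase genes 9 fell, led by RRM2 (-0.83 ± 0.02). The unfolded protein response list fell in 10 of 20 genes, with SDF2L1 at -1.04 ± 0.02. Interferon genes went both ways, with 14 of 31 falling (CMPK2, -1.43 ± 0.05) and IFIT2 (1.38 ± 0.16), IFIH1 (1.18 ± 0.02) and OAS3 (0.50 ± 0.02) rising. B cell identity genes also split, with 6 rises, led by the complement receptor CR2 (2.51 ± 0.05), and 3 falls (POU2AF1, SYK and FCRLA, -1.06, -0.85 and -0.72). Of the germinal centre genes 5 rose and 4 fell. Markers of other cell types, each at a mean of 1.02 CPM or less, went both ways: of the 2 fibroblast markers COL1A1 rose (3.69 ± 0.15) and PDGFRB fell (-1.02 ± 0.21), myeloid CSF1R (1.03) and the NK gene PRF1 (0.67) rose, and NK KLRF1 (-1.60), T cell CD3E (-1.25), epithelial KRT8 (-0.99) and EPCAM (-0.64) and erythroid ALAS2 (-0.59) fell. Oxidative phosphorylation genes were called in 0 of 38 cases.

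By edgeR, 6585 of 21477 genes were called, 3351 higher and 3234 lower. High cells had more UMIs, a median of 33549 ± 3882 against 22778 ± 2524 in low cells (SD, n = 4), with 4.66% against 4.27% mitochondrial and 17.0% against 19.1% ribosomal protein UMIs. The low range ended at 5 score UMIs and the high range began above 16 or 17, and 18.8% to 20.5% of the cells of a library lay within 1 UMI of the lower bound and 6.64% to 7.58% within 1 of the upper.

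**Figure D1:**
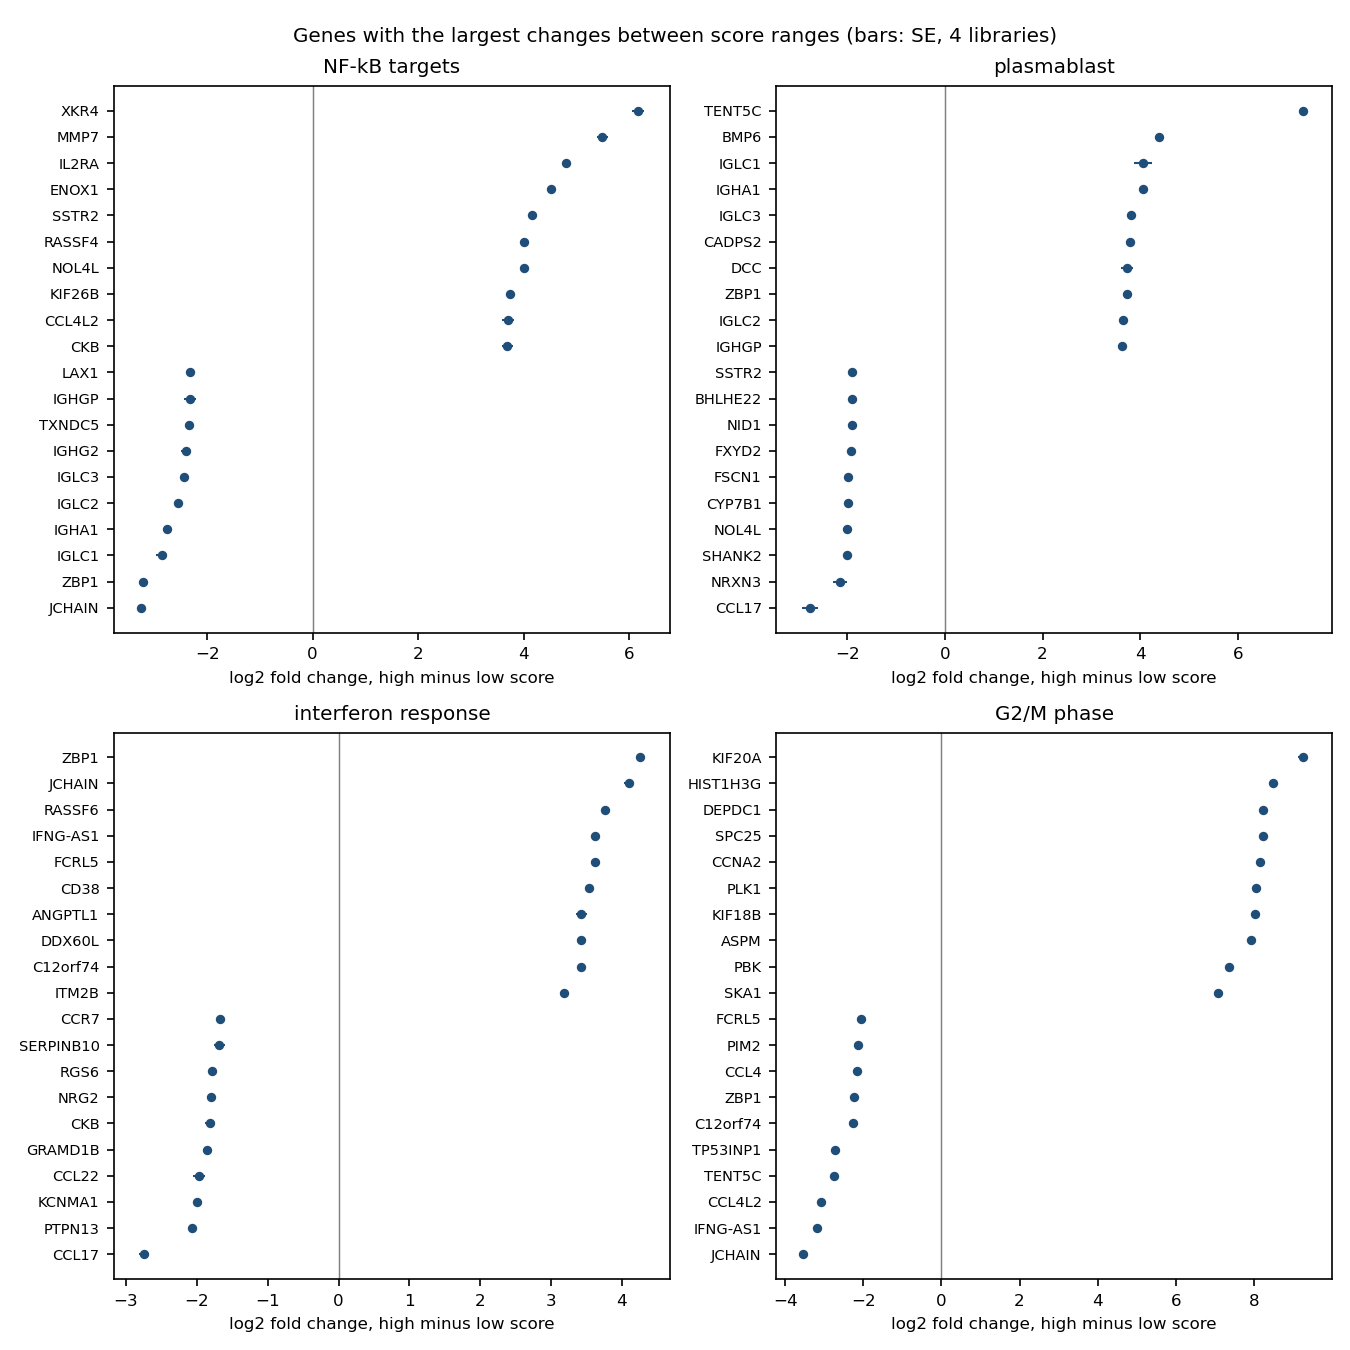
Log2 differences in CPM between cells with a high and a low score for the 10 largest rises and 10 largest falls of each comparison, with bars for the SE over 4 libraries. The panel of the G2/M score reaches the largest rise, 9.24 for KIF20A.

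Cells rich in plasmablast transcripts expressed more immunoglobulin and unfolded protein response genes and fewer heat shock genes, and most NF-kB targets fell. TENT5C, a poly(A) polymerase that stabilises immunoglobulin mRNA (chromosome 1, 117605934 to 117628372), was higher by 7.34 ± 0.07, from 0.161 to 25.6 CPM. BMP6, a bone morphogenetic protein, was higher by 4.39 ± 0.04, IGHA1 by 4.06 ± 0.02, from 99.9 to 1594 CPM, and IGLC1 by 4.06 ± 0.18. CCL17, a chemokine that attracts T cells (chromosome 16, 57404767 to 57416062), fell by 2.77 ± 0.17, from 35.8 to 4.68 CPM. The actin-bundling gene FSCN1 fell by 1.98 ± 0.07 and the oxysterol hydroxylase CYP7B1 by 1.99 ± 0.06. IGLC3 (3.82), CADPS2 (3.80), DCC (3.74), ZBP1 (3.73), IGLC2 (3.65) and IGHGP (3.62) completed the rises, and NRXN3 (-2.15), SHANK2 (-2.01), NOL4L (-2.00), FXYD2 (-1.92), NID1 (-1.91), BHLHE22 (-1.91) and SSTR2 (-1.89) the falls.

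Of 20 unfolded protein response genes, which raise folding capacity in the endoplasmic reticulum, 16 rose and 0 fell, with DNAJB9 at 2.28 ± 0.04, HSPA5 at 1.78 ± 0.02 and HSP90B1 at 1.61 ± 0.03 (camera adjusted p = 1.1e-12, and adjusted p = 0.275 with an estimated correlation). Immunoglobulin constant genes rose in 12 of 14 cases and V, D and J segments in 104 of 106. Among 31 interferon genes 15 rose, led by IFI6 (1.49 ± 0.04) and ISG15 (1.12 ± 0.02; adjusted p = 1.55e-05, and adjusted p = 0.275 with an estimated correlation). NF-kB targets fell in 16 of 27 cases, with CCL22 at -1.68 ± 0.07, while CCL4 (1.03 ± 0.07) and CCL3 (0.75 ± 0.06) rose (adjusted p = 8.53e-06, and adjusted p = 0.399 with an estimated correlation). S phase genes fell in 13 of 42 cases, including the sliding clamp PCNA by 0.77 ± 0.02, and G2/M genes in 6 of 54. Of 11 heat shock genes 9 fell, led by HSPA1A (-0.82 ± 0.07), and of 22 MYC and ribosome biogenesis genes 7 fell, led by PA2G4 (-0.59 ± 0.02). B cell identity genes split into 5 rises, led by POU2AF1 (1.17 ± 0.02) and CD79A (1.05 ± 0.03), with BLNK (0.75), LYN (0.70) and BLK (0.69), and 5 falls, CR2 (-1.54 ± 0.04), SPIB (-0.91), CD24 (-0.88), BANK1 (-0.57) and EBF1 (-0.55). Of the p53 targets, TP53INP1 (2.73 ± 0.04) and BTG2 (1.57 ± 0.03) rose and PHLDA3 (-0.81), FAS (-0.60) and ZMAT3 (-0.55) fell, and the list's median was -0.13 and its mean 0.06. The glycolysis and hypoxia list had a median of -0.19 and a mean of 0.07, with ADM (4.27 ± 0.18, a mean under 1 CPM), PDK1 (1.41 ± 0.03), ANKRD37 (1.14) and NDRG1 (0.95) rising and the oxygen sensor EGLN3 (-1.25), ENO2 (-1.06) and ENO1 (-0.54) falling. S100A9, a myeloid marker, fell by 2.50 ± 0.24, from 2.99 to 0.526 CPM, as did COL1A1 (-1.43), CSF1R (-0.78), NKG7 (-0.57) and KRT8 (-0.53), while KLRF1 (1.32), CD3E (0.87), EPCAM (0.79), PDGFRB (0.76) and ALAS2 (0.62), all under 1 CPM, rose.

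In total edgeR called 5752 of 21115 genes, 2894 higher and 2858 lower, and the 90th against the 10th percentile of the score gave 9537. Median UMIs were 23986 ± 3115 in high and 27523 ± 2538 in low cells (SD, n = 4), with 4.16% against 4.36% mitochondrial and 17.3% against 19.6% ribosomal protein UMIs. Within 1 UMI of the lower bound of 4 score UMIs lay 24.8% to 26.0% of the cells, and 10.4% to 13.2% lay within 1 of the upper bound.

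Cells with a high interferon response score expressed more plasmablast, B cell identity and immunoglobulin genes and fewer replication and ribosome biogenesis genes. ZBP1, itself induced by interferon (chromosome 20, 57603846 to 57620576), was higher by 4.26 ± 0.06, from 1.82 to 35.0 CPM. JCHAIN was higher by 4.10 ± 0.07, from 66.7 to 1162 CPM, and CD38, an ectoenzyme of plasma cells (chromosome 4, 15778275 to 15853230), by 3.53 ± 0.06. CCL17 fell by 2.74 ± 0.07, CCL22 by 1.97 ± 0.08 and the lymph node homing receptor CCR7 by 1.67 ± 0.05. Further rises were RASSF6 (3.76), the antisense RNA IFNG-AS1 (3.62), the Fc receptor-like gene FCRL5 (3.62), ANGPTL1 (3.43), the helicase gene DDX60L (3.43), C12orf74 (3.43) and ITM2B (3.19). Further falls were PTPN13 (-2.07), the potassium channel KCNMA1 (-1.99), GRAMD1B (-1.86), CKB (-1.82), NRG2 (-1.80), RGS6 (-1.79) and SERPINB10 (-1.68).

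The plasmablast list rose in 14 of 20 genes, with CD27 at 2.23 ± 0.03 (camera adjusted p = 7.49e-08, and adjusted p = 0.257 with an estimated correlation). Of 24 B cell identity genes 17 rose, led by CD24 (2.20 ± 0.05) and CD72 (1.65 ± 0.05), and CR2 fell by 1.01 ± 0.04 (adjusted p = 1.85e-10, and adjusted p = 0.257 with an estimated correlation). Germinal centre genes rose in 6 of 11 cases, among them the transcription factors MEF2B (1.40 ± 0.04) and LMO2 (1.39 ± 0.03). Of 15 MHC class I and antigen processing genes 6 rose, with HLA-E at 0.79 ± 0.01, B2M at 0.75 ± 0.01 and the peptide transporter TAP1 at 0.69 ± 0.02 (adjusted p = 2.74e-08, and adjusted p = 0.241 with an estimated correlation). Immunoglobulin constant genes rose in 13 of 14 cases, with IGHE the exception at -0.75 ± 0.22, and V, D and J segments in 97 of 102. Of 42 S phase genes 37 fell, with EXO1 at -1.09 ± 0.03, UHRF1 at -1.07 ± 0.03 and CDC6 at -1.07 ± 0.03 (adjusted p = 1.82e-17, and adjusted p = 0.241 with an estimated correlation). G2/M genes fell in 22 of 54 cases, and MYC and ribosome biogenesis genes in 21 of 22, with NOP56 at -0.94 ± 0.01 (adjusted p = 8.83e-14, and adjusted p = 0.241 with an estimated correlation). Heat shock genes fell in 8 of 11 cases, including HSPD1 by 0.81 ± 0.01, and NF-kB targets in 8 of 27. Glycolysis and hypoxia genes fell in 11 of 24 cases and rose in 4, ADM (1.49), EGLN3 (0.93), SLC2A3 (0.81) and PDK1 (0.54). Among p53 targets, TP53INP1 (2.32 ± 0.04), BTG2 (1.90 ± 0.02) and SESN1 (0.77 ± 0.04) rose, and the list's median was -0.04 and its mean 0.15. CDH1, an epithelial marker, fell by 1.00 ± 0.05, from 9.35 to 4.79 CPM. Of the other markers, all under 1 CPM, GNLY (-1.76), COL1A1 (-1.53) and CSF1R (-0.89) fell and KLRF1 (1.52), PRF1 (1.03) and CD3E (0.81) rose.

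The interferon comparison called 6456 of 20876 genes in edgeR, 3493 higher and 2963 lower. High cells were shallower, with a median of 20909 ± 2234 UMIs against 35155 ± 3838 in low cells (SD, n = 4). Mitochondrial genes took 4.01% ± 0.0705 of the UMIs in high and 4.88% ± 0.0333 in low cells, and ribosomal protein genes 16.8% against 19.2%. The cells within 1 UMI of a bound made up 17.2% to 19.4% of a library at the lower bound of 6 or 7 score UMIs and 7.42% to 8.57% at the upper.

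Cells with a high G2/M score expressed more replication, ribosome biogenesis and heat shock genes and fewer NF-kB, interferon, plasmablast and B cell identity genes. KIF20A, a mitotic kinesin (chromosome 5, 138178719 to 138187715), was higher by 9.24 ± 0.11, from 0.0399 to 23.4 CPM. CCNA2, cyclin A2 (chromosome 4, 121816444 to 121823933), was higher by 8.15 ± 0.05, and PLK1, a mitotic kinase (chromosome 16, 23677656 to 23690367), by 8.04 ± 0.04. JCHAIN fell by 3.54 ± 0.03, from 1467 to 118 CPM, IFNG-AS1 by 3.19 ± 0.03 and TP53INP1 by 2.72 ± 0.06. The histone gene HIST1H3G (8.48), DEPDC1 (8.24), the kinetochore gene SPC25 (8.23), KIF18B (8.01), the spindle gene ASPM (7.92), PBK (7.37) and SKA1 (7.08) also rose. CCL4L2 (-3.08), TENT5C (-2.75), C12orf74 (-2.25), ZBP1 (-2.24), CCL4 (-2.15), the survival kinase PIM2 (-2.13) and FCRL5 (-2.06) also fell.

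All 42 S phase genes rose, with RRM2 at 6.65 ± 0.05, E2F8 at 5.52 ± 0.06 and CENPU at 4.16 ± 0.03 (camera adjusted p = 1.28e-19, and adjusted p = 0.222 with an estimated correlation). Of 22 MYC and ribosome biogenesis genes 17 rose, including CAD (1.40 ± 0.03), which starts pyrimidine synthesis (adjusted p = 8.61e-10, and adjusted p = 0.222 with an estimated correlation). Heat shock genes rose in 8 of 11 cases, with HSP90AA1 at 1.29 ± 0.02, and glycolysis and hypoxia genes in 13 of 24, with lactate dehydrogenase A (LDHA) at 1.18 ± 0.01, while NDRG1 (-1.77) and ALDOC (-0.53) fell and PDK1 fell by 1.00. Of 38 oxidative phosphorylation genes 6 rose, led by CYC1 (0.85 ± 0.03). NF-kB targets fell in 18 of 27 cases, with TNFAIP2 at -1.82 ± 0.04 and CD83 at -1.77 ± 0.02 (adjusted p = 1.03e-10, and adjusted p = 0.222 with an estimated correlation). The plasmablast list fell in 15 of 20 genes, with CD27 at -1.85 ± 0.02, and the interferon list in 17 of 31, with IFI6 at -1.58 ± 0.03 (adjusted p = 5.04e-09 and 1.32e-10, and adjusted p = 0.222 for both with an estimated correlation). Of 24 B cell identity genes 17 fell, led by BACH2 (-1.62 ± 0.07), a repressor of plasma cell differentiation. Immunoglobulin constant genes fell in 11 of 14 cases and V, D and J segments in 99 of 106. Immediate early EGR3 (-2.01 ± 0.09), NR4A1 (-1.47), DUSP2 (-1.37) and ZFP36 (-1.19) fell. MHC class II genes HLA-DOB (-1.13), HLA-DMA (-0.61) and HLA-DPB1 (-0.56) fell as well. The other 10 of 13 were also lower with an adjusted p under 0.05 in edgeR, but stayed under the size threshold of a call. Of the markers of other cell types, KLRD1 (-1.72), CD3E (-0.98), PRF1 (-0.89) and CD3D (-0.58) fell and S100A9 (0.90) rose, each under 2 CPM.

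With edgeR, 7838 of 20606 genes were called, 3394 higher and 4444 lower, or 43.3% higher. Scaling by library totals alone made 33.8% of the calls higher and moved the median over all genes from -0.02 to -0.12. High cells were deeper, with a median of 43955 ± 4994 UMIs against 18142 ± 1578 in low cells (SD, n = 4). Mitochondrial genes took 4.97% ± 0.0681 of the UMIs in high and 3.79% ± 0.0371 in low cells, and ribosomal protein genes 17.1% against 18.1%. Of the cells of a library, 16.0% to 17.3% lay within 1 UMI of the lower bound of 4 score UMIs and 5.48% to 6.19% within 1 of the upper.

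**Figure D2:**
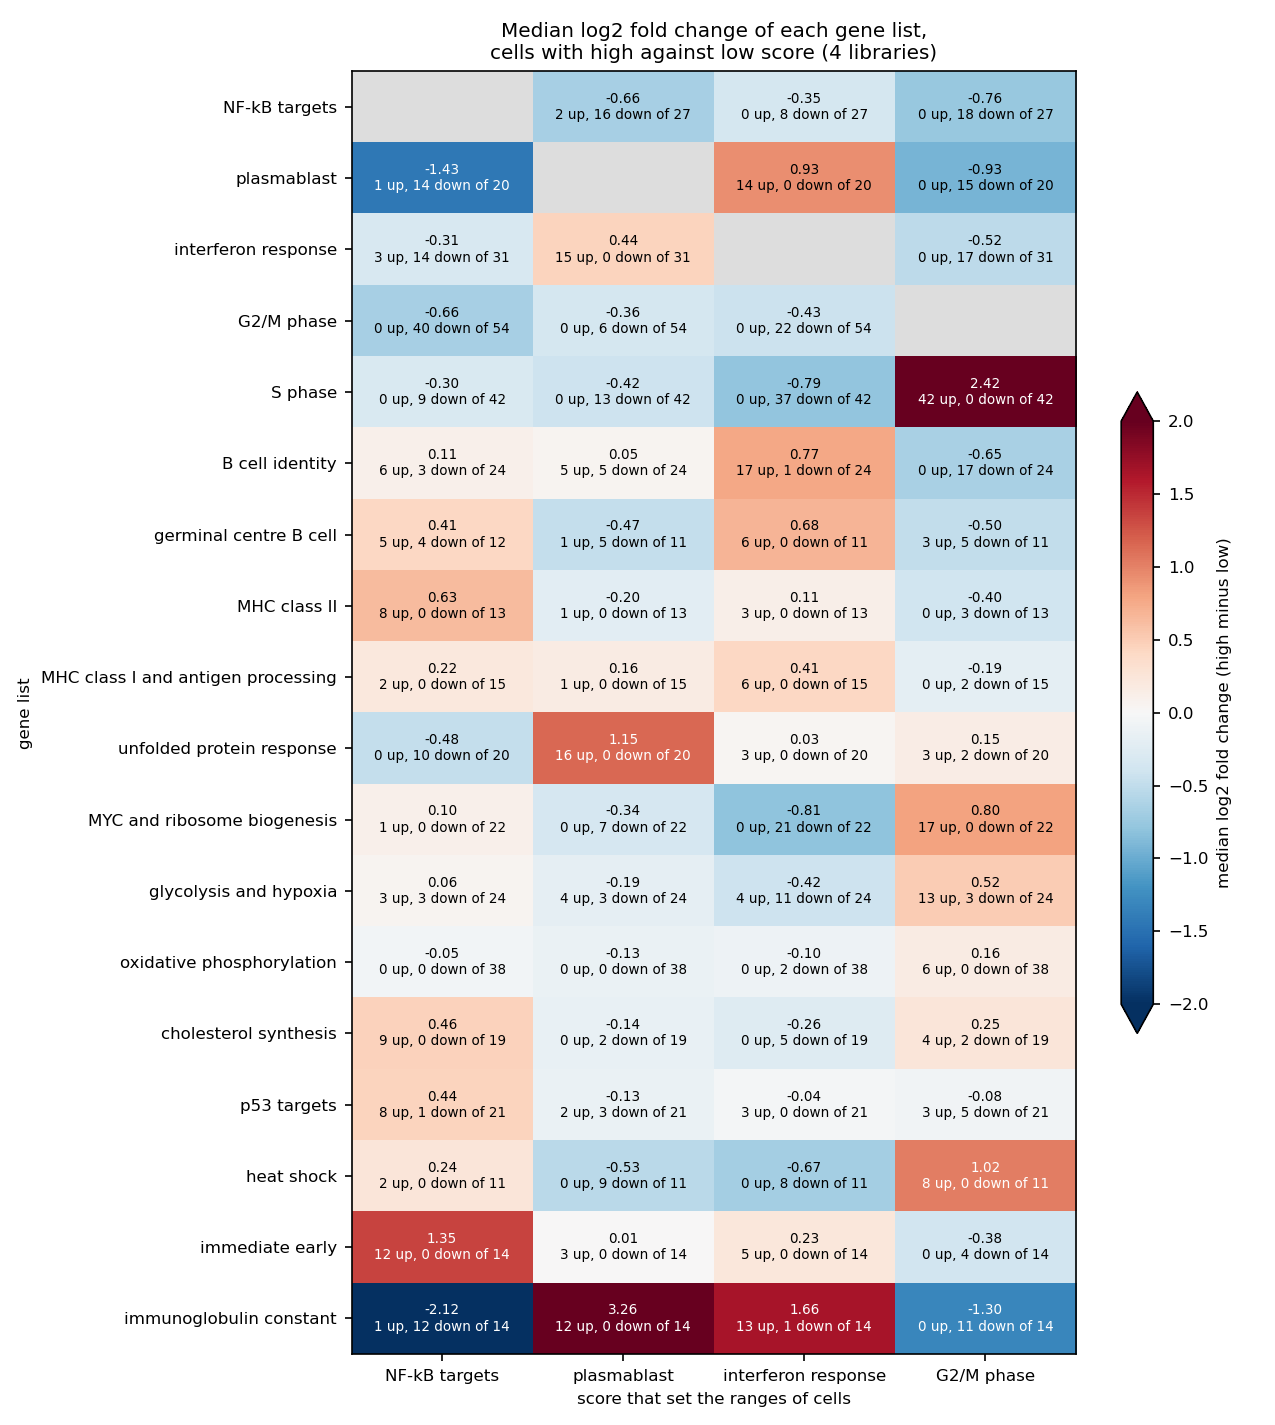
Median log2 difference between high- and low-score cells for each gene list (vertical) in the 4 comparisons (horizontal), as colour, with the numbers of called genes that rose and fell in each cell. The S phase list has 42 rises and 0 falls by G2/M score and 0 rises and 37 falls by interferon score.

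Counts of list members adjusted over the list alone were equal to those above for every state list except glycolysis and hypoxia with the interferon score, where 5 rather than 4 rose. Over the 4 comparisons, camera passed 51 of 68 list tests with the preset correlation, 0 with an estimated correlation, and fry 65. For V, D and J segments with the NF-kB score, adjustment over the group alone gave 2 rises and 102 falls in place of 1 and 101.

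A second question was which genes varied with the same states from line to line. Slopes are log2 units per SD of the score across 384 lines, with their SE. With the NF-kB score, MMP7 had a slope of 0.76 ± 0.12, XKR4 of 0.61 ± 0.10 and CKB of 0.50 ± 0.05 (adjusted p = 1.34e-08, 6.02e-08 and 7.91e-17). Positive slopes were also found for the integrin gene ITGA1 (0.39), the guidance receptor ROBO1 (0.39), RASSF4 (0.39), PSTPIP2 (0.37), the glypican GPC5 (0.37), CLIC2 (0.37) and the interleukin-1 receptor IL1R1 (0.37). IGHGP, an immunoglobulin pseudogene, had the most negative slope, -0.61 ± 0.12, followed by IGHA2 (-0.54 ± 0.12), IGHA1 (-0.48 ± 0.10), KCNMB2 (-0.46), IGLC1 (-0.39), EYA2 (-0.38), IGHG2 (-0.32), MEIS2 (-0.31), TOX (-0.31) and UCHL1 (-0.29). Of 13 immunoglobulin constant genes 8 had a called negative slope and IGLC7, at a mean of 5.62 CPM, a positive one (0.82 ± 0.17). Among the list members, DERL3 (-0.30 ± 0.05) and TXNDC5 (-0.22 ± 0.03) of the plasmablast list, IFIT2 (0.21), CR2 (0.22) and ATF3 (0.20) were called. Most list members had slopes under the 0.2 threshold: 48 of 52 G2/M genes and 17 of 19 plasmablast genes had a negative slope with an adjusted p under 0.05, and 0 and 2 of them were called. In total 228 of 10790 genes were called in edgeR, 180 with a positive slope, and scoring lines by summed counts gave 146.

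With the plasmablast score, IGHA1 rose by 1.10 ± 0.10 per SD, IGHG4 by 0.80 ± 0.10 and IGLC1 by 0.75 ± 0.12 (adjusted p = 1.74e-22, 1.08e-12 and 1.78e-08). IGHA2 (0.70), IGLC2 (0.67), IGHG1 (0.65), IGHG3 (0.62), IGHGP (0.61), the transcription cofactor EYA2 (0.61) and IGLC3 (0.59) followed. The chemokine CXCL10 had the most negative slope, -0.75 ± 0.11, and ANK3 (-0.73), MMP7 (-0.72), XKR4 (-0.67), coagulation factor F13A1 (-0.66), PTPRK (-0.65), SHANK2 (-0.65), GUCY1B1 (-0.63), NFIB (-0.60) and the antiviral gene IFITM3 (-0.60) came next. Of 13 constant genes 9 had a positive slope, while IGLC7 (-0.42 ± 0.16) and IGHD (-0.28 ± 0.06), the IgD constant region, had negative ones. Unfolded protein response genes had a called positive slope in 7 of 20 cases, with DNAJB9 at 0.31 ± 0.02, HSPA5 at 0.27 ± 0.02 and HSP90B1 at 0.27 ± 0.01, and 19 of the 20 had a positive slope with an adjusted p under 0.05. Of 9 V, D and J segments 6 had a positive slope. BACH2 (0.29), PDK1 (0.26) and TP53INP1 (0.35) were positive, and BANK1 (-0.44), RGS13 (-0.39), EGLN3 (-0.37), CD24 (-0.24), TNFAIP2 (-0.24), CR2 (-0.22) and IFIT2 (-0.21) negative. The edgeR calls numbered 581 of 10798 genes, 193 positive and 388 negative.

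With the interferon score, IGHGP rose by 0.88 ± 0.13 per SD, MMP7 by 0.80 ± 0.13 and DDX60L by 0.57 ± 0.03 (adjusted p = 2.95e-09, 2.26e-08 and 2.88e-44). The adhesion gene CHL1 (0.54), CD96 (0.53), NPSR1-AS1 (0.52), MYRIP (0.52), CCDC198 (0.51), SHANK2 (0.50) and PTPRK (0.50) followed. HECW2, a ubiquitin ligase, fell by 0.69 ± 0.08, and CREB5 (-0.62), RGS6 (-0.59), P3H2 (-0.54), GRAMD1B (-0.51), XKR4 (-0.50), KCNMA1 (-0.49), the interleukin-12 receptor IL12RB2 (-0.46), DPF3 (-0.45) and MICAL3 (-0.45) also had negative slopes. CD24 (0.39 ± 0.06), EGLN3 (0.35), CD38 (0.27) and IGLC7 (0.66) were called positive and CCL17 (-0.38), IGHG2 (-0.38), CDH1 (-0.51), GCSAM (-0.25), BANK1 (-0.25), CR2 (-0.22) and ANKRD37 (-0.21) negative. Of 15 MHC class I genes 14 had a positive slope with an adjusted p under 0.05, and 0 reached 0.2. Ribosomal protein genes showed the opposite in 78 of 82 cases, with a median slope of -0.04, and 0 were called. The calls numbered 350 of 10786 genes, 221 positive, and 545 without the line total as a covariate.

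With the G2/M score, NFIB rose by 0.48 ± 0.11 per SD, PLK1 by 0.31 ± 0.02 and DEPDC1 by 0.31 ± 0.02 (adjusted p = 0.000359, 1.74e-54 and 4.92e-54). IGLC1 (0.40), CD96 (0.37), PLXDC2 (0.36), SOX5 (0.35), SNTB1 (0.33), MEIS2 (0.31) and NCKAP5 (0.29) were also positive. TMEM163 (-0.50 ± 0.12), P3H2 (-0.47), RGS6 (-0.44), IGHG2 (-0.43), PRKCH (-0.40), AFF3 (-0.40), NTNG1 (-0.39), XKR4 (-0.36), CLIC2 (-0.33) and HECW2 (-0.33) were negative. RRM2 (0.20 ± 0.02) was the called gene among 42 S phase genes, of which 33 had a positive slope with an adjusted p under 0.05. Outside the immunoglobulin list, MYBL1 (0.20) and TNFAIP2 (-0.23) were the other called list members. Within it, IGLC1 and IGHG2 passed narrowly in edgeR (adjusted p = 0.0436 and 0.03). With adjustment over that list alone, 0 of its 13 genes were called. The edgeR calls numbered 147 of 10765 genes, 92 positive, against 350 without the line total as a covariate and 70 with the S phase score added. Without the total, the slopes of NFIB, CD96, PLXDC2, SOX5, SNTB1, NCKAP5, P3H2, RGS6, AFF3, NTNG1 and HECW2 turned sign, and with limma voom 32.3% of 192 calls were positive against 62.6% here.

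The same cells underlie both tables, so the cell and line results are not independent. Of the genes called across lines, 212 with the NF-kB score, 450 with the plasmablast score, 262 with the interferon score and 124 with the G2/M score were also called in cells, where independent lists would share 48.9, 110.3, 86 and 46.7. The sign was the same for 99.5%, 97.6%, 97.3% and 96.0% of them. RASSF6, ZDHHC14 and TRPS1 were higher in plasmablast-high cells (1.65, 0.68 and 0.54) and had negative plasmablast slopes (-0.21, -0.36 and -0.26). ADAM19, a membrane protease, and IGHG2 were higher in interferon-high cells (1.07 and 1.38) with negative slopes (-0.24 and -0.38). IGLC1 and CD96 were lower in G2/M-high cells (-2.02 and -1.02) with positive slopes, and MYH10 was higher (0.59) with a negative slope (-0.25). These opposite genes were picked out after their values were seen. Spearman's rho across genes between the cell differences and the line slopes was 0.777, 0.591, 0.566 and 0.635, and genes are not independent replicates.

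Across the 384 lines, the scores of the 18 state lists rose and fell together in 55 pairs and in opposite directions in 53, of 153 pairs tested by permutation. MYC and ribosome biogenesis, heat shock and glycolysis formed the closest trio before the line total was taken into account, with r = 0.820 (rho 0.797) between MYC and heat shock, r = 0.805 (rho 0.746) between MYC and glycolysis and r = 0.738 (rho 0.682) between glycolysis and heat shock. Plasmablast and unfolded protein response scores correlated with r = 0.671 (rho 0.648), interferon and MHC class I scores with r = 0.664 (rho 0.650), G2/M and S phase scores with r = 0.623 (rho 0.544), and NF-kB and immediate early scores with r = 0.461 (rho 0.449). Each of these pairs had a permutation p = 1e-05 and an adjusted p = 2.39e-05. Without the 2 lines farthest from the median they gave r = 0.800, 0.785, 0.711, 0.667, 0.657, 0.580 and 0.439 in the order named. Given the line total, the same pairs had a partial r of 0.530, 0.529, 0.415, 0.724, 0.616, 0.380 and 0.453 (permutation, adjusted p = 4.94e-05 for each). Plasmablast with unfolded protein response and interferon with MHC class I were then closer than any pair of the trio.

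Among the 4 states, the NF-kB score was opposed to the plasmablast score (r = -0.288, rho -0.230, -0.262 without the 2 farthest lines, and -0.138 with summed counts as score, permutation adjusted p = 0.0086) and to the G2/M score (r = -0.288, rho -0.353, -0.348 without them; permutation p = 1e-05 and adjusted p = 2.39e-05 for both r). The interferon score was opposed to the G2/M score (r = -0.250, rho -0.253, -0.261 without the 2 farthest lines; permutation p = 2e-05, adjusted p = 4.5e-05), but given the line total the partial r was -0.0144 (permutation, adjusted p = 0.832). NF-kB and interferon (r = -0.0406, rho -0.0200, permutation adjusted p = 0.478), plasmablast and interferon (r = 0.0749, rho 0.0024, adjusted p = 0.177) and plasmablast and G2/M (r = -0.0439, rho -0.0666, adjusted p = 0.440) did not pass. These 3 calls depend on the score and covariates, since summed counts gave r = 0.242 and -0.152 for the 2 plasmablast pairs and the cycle scores as covariates gave -0.134 for NF-kB and interferon (permutation, adjusted p = 3.52e-05, 0.00398 and 0.0172). Among cells within a library, Spearman's rho over the 4 libraries was 0.245 to 0.296 for plasmablast and interferon scores, -0.278 to -0.254 for interferon and G2/M, -0.250 to -0.226 for plasmablast and G2/M, -0.159 to -0.132 for NF-kB and G2/M, -0.139 to -0.0779 for NF-kB and interferon and -0.134 to -0.0229 for NF-kB and plasmablast. The total count of a line, which moves with several scores, was no labelled batch, and given it 83 of the 153 pairs passed, 71 of them with the sign and call found without it. Of the 108 pairs that passed without the total, 9 turned sign given it, and 2 of these passed with the opposite sign. By Spearman's rho 110 pairs passed.

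**Figure D3:**
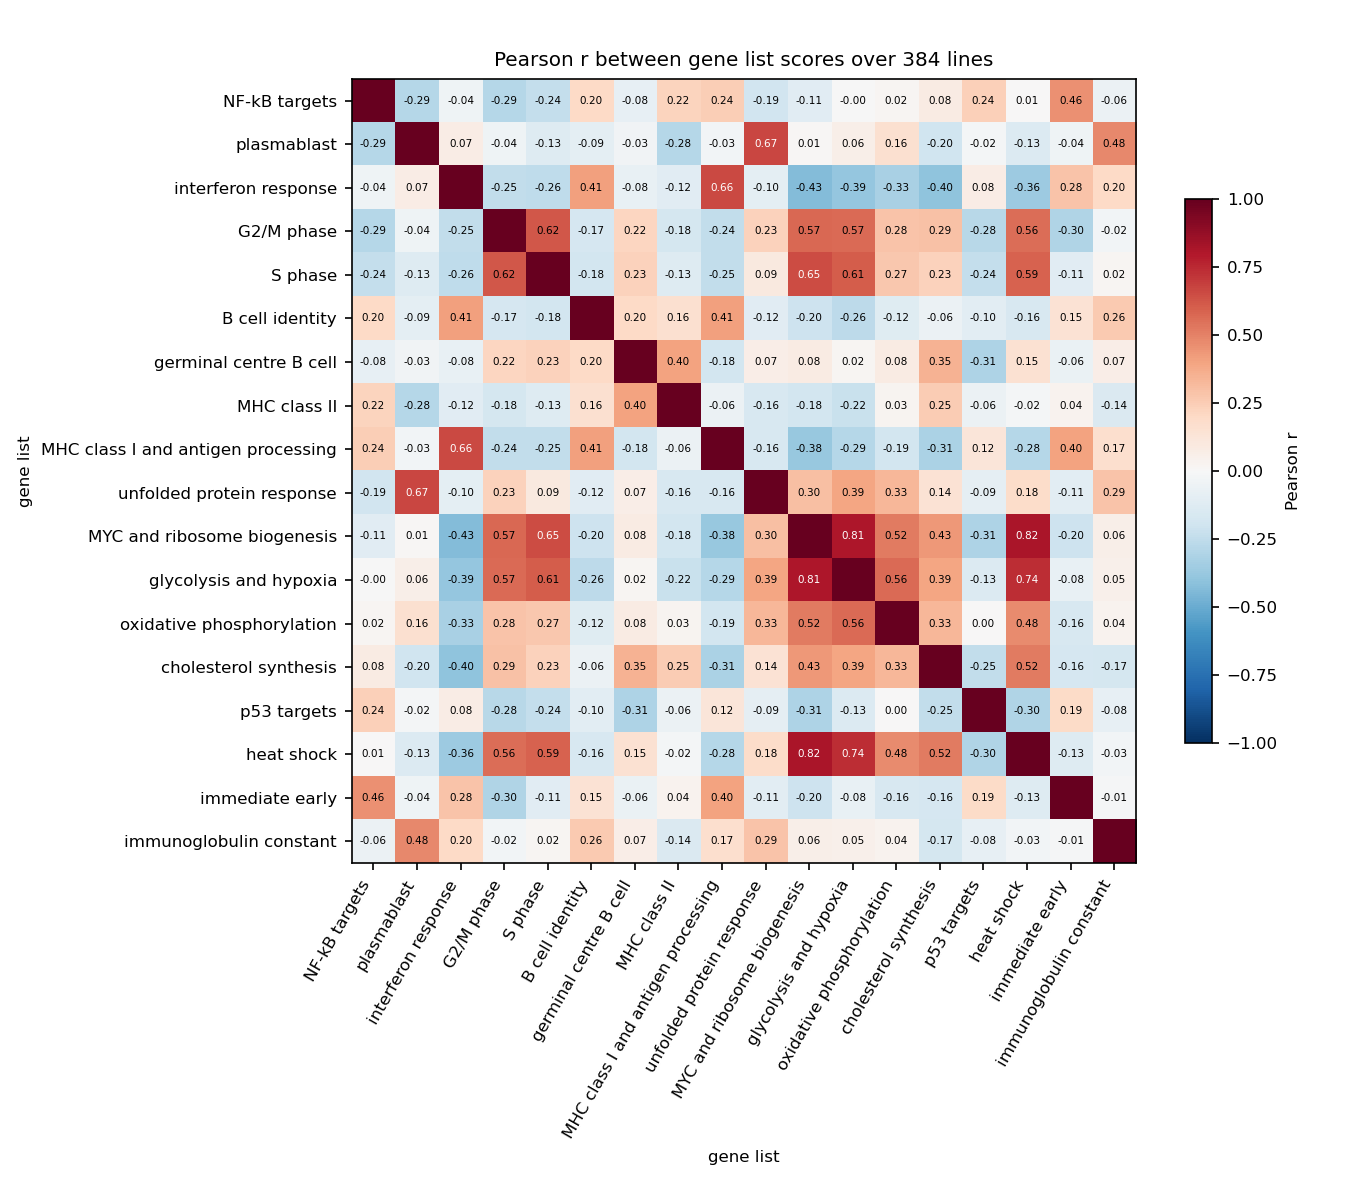
Pearson's r between the scores of 18 gene lists across 384 lines, as colour, with lists on both axes. The block of MYC, glycolysis and heat shock lists holds r from 0.738 to 0.820.

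Immunoglobulin constant genes varied widely between lines, with a median coefficient of variation of 1.22 over 12 genes against 0.102 over 9130 genes. Of the genes that the naming rule admits, which leaves out V, D and J segments and clone-named or LINC loci, EYA2 (chromosome 20, 46894624 to 47188844) had a coefficient of variation of 1.70, with a median of 2.32 CPM and a 95th percentile of 68.0 CPM over lines. MMP7 (chromosome 11, 102520508 to 102530753) had 1.68, IGHGP 1.67, IGHG2 1.63, the semaphorin SEMA5A 1.56, CXCL10 1.51, IGHA2 1.46, HLA-DQA2 1.46, IGLC1 1.41, IGHA1 1.38, XKR4 1.37, IGLC3 1.36, the glucuronosyltransferase UGT2B17 1.32, the collagen hydroxylase P3H2 1.30, PLXDC2 1.29, ANK3 1.28, SOX5 1.27, IGHG4 1.27, ROBO1 1.26 and LRMDA 1.24. Among these 20 genes, a moment estimate put IGHG2 first at 4.55, followed by IGHGP at 2.89 and ROBO1 at 2.32, with EYA2 at 1.97 and UGT2B17 at 0.855. Of the 20, 13 were also among the 20 largest by that estimate. Germinal centre genes had a median of 0.445 over 5 genes, MHC class II genes 0.272 over 12, plasmablast genes 0.265 over 18, NF-kB targets 0.220 over 27 and interferon genes 0.210 over 29. G2/M genes had 0.128 over 51, ribosomal protein genes 0.0897 over 82, MYC and ribosome biogenesis genes 0.0849 over 22 and oxidative phosphorylation genes 0.0612 over 38. Within the lists, CCL17 (0.954) varied most among NF-kB targets, IFI27 (0.916) among interferon genes, CD24 (0.768) among B cell identity genes and EGLN3 (0.760) among glycolysis and hypoxia genes. No p-value is attached to these coefficients. Each line entered as the sum of its cells, without replicates of a line. Lasting differences between lines and the sampling of cells within a line were therefore not separated, here or in the slopes.

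Light chains separated most cells. Kappa took at least 0.9 of the light chain UMIs in 54.0% ± 1.31 of the cells with 10 or more, lambda did in 31.8% ± 3.21, and 14.2% ± 4.39 were mixed (SD, n = 4). Replicates 1 to 4 had 20.4%, 11.2%, 14.2% and 11.1% mixed cells, with 95% intervals of 19.6% to 21.4%, 10.6% to 11.7%, 13.6% to 14.9% and 10.5% to 11.7%. Asking for 30 UMIs gave 9.63% mixed and bounds of 0.95 and 0.05 gave 27.6%. Over lines, the kappa share had a median of 0.601 and ran from 0.0435 at the 5th to 0.980 at the 95th percentile. By the same bounds, 55 lines were kappa, 33 lambda and 296 of 384 in between.

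IGHM, the constant region of IgM, was the leading heavy chain isotype. Among the 6988, 12107, 9440 and 10146 cells of replicates 1 to 4 with at least 10 heavy chain constant UMIs, it was the largest isotype and took at least 50% of these UMIs in 41.2% ± 0.324 of cells (SD, n = 4), followed by IGHA1 in 13.7% ± 0.131, IGHG1 in 11.8% ± 2.46 and IGHG3 in 7.77% ± 3.43. Over lines, IGHM had a median share of 54.8%, IGHG1 of 7.38%, IGHA1 of 5.07%, IGHG3 of 3.96% and IGHD of 3.36%. The IGHM share was at least 50% in 204 of 384 lines, the IGHA1 share in 33 and the IGHG1 share in 15. In 124 lines no isotype reached 50%, and in 32 lines an isotype reached 90%.

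**Figure D4:**
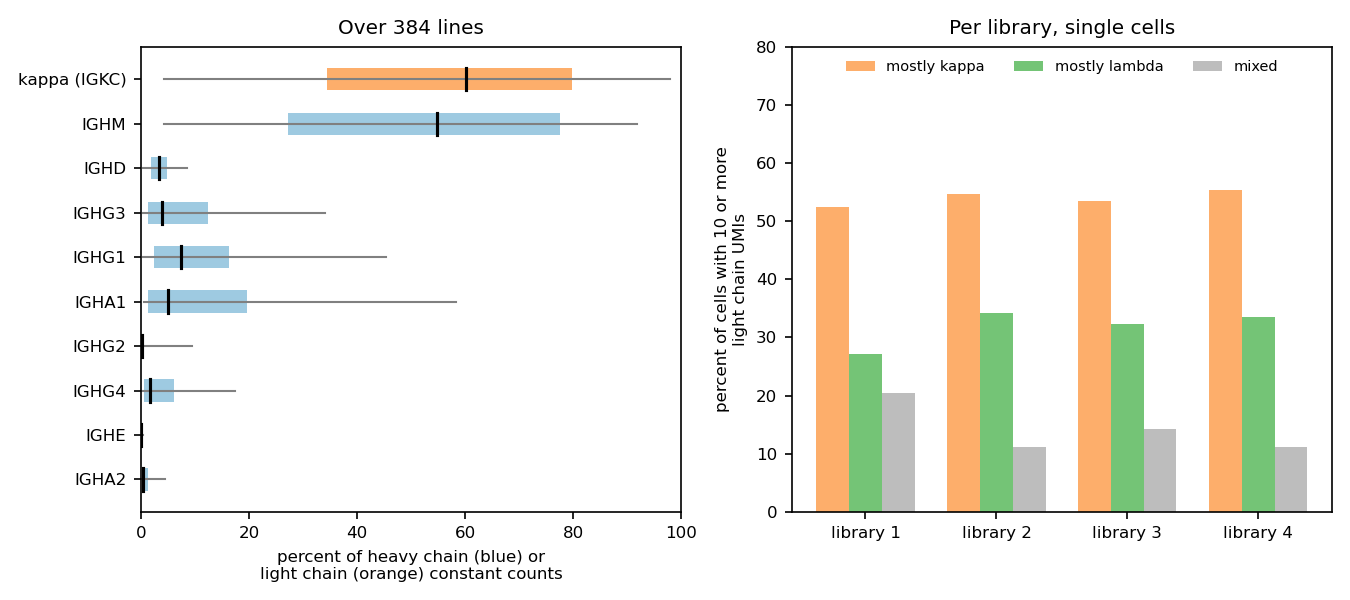
Left, the kappa share and the heavy chain isotype shares in percent over 384 lines, with thin lines from the 5th to the 95th percentile, boxes from the 25th to the 75th and ticks at the median; right, percent of cells with kappa, mixed and lambda light chains in each library. IGHM has the highest median isotype share, 54.8%, and replicate 1 the most mixed cells, 20.4%.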

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

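The 2 tests of droplets with cells of 2 lines and the tests of empty droplets, of library spread over line spread, of library preparation and of the minor light chain in cells of each kind were chosen after the result was seen, and the other tests before. Of 62 groups of 4 library values, 4 held a library far from the other 3 by Dixon's test, where 3.1 would by chance. Germinal centre genes stood at 364.286 CPM in replicate 1 against 374.686 to 375.062 in the others. Cholesterol synthesis genes stood at 1259.63 CPM in replicate 3 against 1313.08 to 1323.82. T cell markers summed to 55.157 CPM in replicate 2 against 53.241 to 53.5. Epithelial markers summed to 9.727 CPM in replicate 3 against 8.339 to 8.562. The labels give 1 group, so no biological explanation was tested for any pattern below.

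Cells with both kappa and lambda light chains were more frequent in replicate 1, at 20.4% against 11.1% to 14.2%. Free RNA in the droplets may account for part of this excess and stays open, since at 1000 or more light chain UMIs only 1.956% of the cells of replicate 1 were mixed (8 of 409, exact interval 0.848% to 3.82%) against 3.55% to 4.66% in the others. Replicate 1 had a 5th percentile of 209 light chain CPM per cell against 89.3 to 94.0. The minor chain was counted only in cells with at least 1000 light chain UMIs, 176 lambda and 225 kappa cells in replicate 1. Its lambda cells held a median of 4 kappa UMIs against 2 in the other libraries. Its kappa cells held a median of 8 lambda UMIs against 7 to 8, where free RNA of both chains would have raised both. A higher rate of droplets with cells of 2 lines is unlikely as the whole source, since it would raise the share at every light chain depth, and the ratio of replicate 1 to the others was 1.70 in all cells tested (95% interval 1.61 to 1.79) and 1.054 at 300 or more light chain UMIs (0.847 to 1.31). How many mixed cells are such droplets stays open: the median UMIs of mixed cells in replicate 1 were 1.12 times those of single-chain cells, 1.35 times at 300 and 1.85 times at 1000 light chain UMIs, and 28.4% of its cells over 2 times the median UMIs were mixed against 19.4% of the others.

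Shallow cells under 3500 UMIs had 0 mitochondrial UMIs in 77.3% ± 5.16 of cases against 7.17% ± 2.55 of the deeper cells (SD, n = 4). Only 3.91% of the shallow cells with 0 had the 10 light chain UMIs that a test of empty droplets with free RNA needs, so for the rest the explanation stays open. Among those that had them, empty droplets are unlikely in replicates 2 to 4, where at most 9.804% held both light chains (5 of 51, with the highest exact upper limit, in replicate 3, at 22.1%), while replicate 1 had 33.333% (2 of 6), too few to tell. Nuclei without cytoplasm are unlikely too, since the nuclear RNA MALAT1 was at 0.377 to 0.604 times its level in deeper cells. Ribosomal protein genes took 42.2% of the UMIs of shallow cells against 17.8% in deeper cells, with RPL31 higher by a log2 ratio of 1.71 ± 0.0834 (SD, n = 4). The largest falls were those of MKI67 (-3.82 ± 0.637), SYNGR2 (-3.59 ± 0.605) and PDIA6 (-3.56 ± 0.686), genes of different kinds. The largest rises were mostly of ribosomal protein genes, with BCL2A1 among them (1.41 ± 0.277). All these values are shares of UMIs, so they move with this shift in composition.

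Genes differed between libraries to unequal degrees, and whether different proportions of the lines cause all of it stays open. NDUFB1, RPS29, RBMX, ATP5ME, EIF5B and SLC27A4, 6 of 2034 genes, had a library spread over 1.5 times their line spread (NDUFB1 15.6% against 7.11%). The line spread leaves out what goes with the line total, which proportions of lines would carry, and the library spread rests on 4 values. These 6 genes therefore do not exclude different proportions. The test across genes could not tell, as library and line spread had a rho of 0.26 across 1941 genes. Library preparation could not be told either, with the spread of ribosomal and mitochondrial genes at 1.165 times that of matched genes (quartiles 0.878 and 1.63).

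Labels of high and low were also exchanged over the 8 sums of each score. The sums are paired by library, and 8 splits part every library as the real one does, too few for a share under 0.05. The real split gave 6585 calls for the NF-kB score, 5752 for the plasmablast score, 6456 for the interferon score and 7838 for the G2/M score, and 1 of the 8, the real split, gave as many. The highest other count was 0 for each, also over the 24 splits that part fewer libraries.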

How the results depend on the processing

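Most gene results kept direction and call. Of 3738 alternative values for named genes in cells, 3710 were the same, 27 lost the call and 1 turned. For lines 817 of 888 were the same, 60 lost the call and 11 turned. Without 1 library, calls ran from 6269 to 6600 (NF-kB), 5309 to 5694 (plasmablast), 6100 to 6597 (interferon) and 7501 to 7981 (G2/M). Without the library block they were 6573, 5734, 6447 and 7840. The cause was not tested for any change below, except where fewer or more genes tested show it. The 90th against the 10th percentile gave 9537 plasmablast calls. E2F8, lower in NF-kB-high cells (-0.64), was higher by 0.79 among cells with low cycle scores. E2F8 is a member of the S phase list, so its own counts helped to pick these cells. Camera with an estimated correlation passed 0 lists.

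Across lines, a minimum of 1 CPM, with more genes tested, gave 515, 1202, 779 and 336 calls. Summed counts as score gave 146 for NF-kB. Without the total covariate there were 545 interferon and 350 G2/M calls, and the S phase score left 70 G2/M calls. Without the total, the G2/M slopes were -0.0249 for NFIB, -0.0364 for CD96, -0.31 for PLXDC2, -0.13 for SOX5, -0.0271 for SNTB1, -0.20 for NCKAP5, 0.0571 for P3H2, 0.0045 for RGS6, 0.23 for AFF3, 0.0107 for NTNG1 and 0.16 for HECW2. NF-kB and interferon scores had a partial r of -0.134 given both cycle scores (permutation, adjusted p = 0.0172). Summed scores gave r = 0.242 for plasmablast and interferon and r = -0.152 for plasmablast and G2/M (permutation, adjusted p = 3.52e-05 and 0.00398). Given the total, interferon and G2/M had -0.0144. With 30 light chain UMIs 56.9% of cells were kappa and 9.63% mixed, and with bounds of 0.95 and 0.05, 46.8% kappa, 27.6% mixed and 25.5% lambda. Mean per-cell CPM, which weighs each cell alike, gave a median list coefficient of 2.79% between libraries and moved 21 of 24 list levels by at least their SD, such as immunoglobulin constant genes from 10244 to 15664 CPM, G2/M genes from 5861 to 4904 and plasmablast genes from 2678 to 3326. Among the 20 most variable genes, the moment estimate moved IGHGP, IGHG2, UGT2B17 and ROBO1.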

Other observations

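Lines with more counts in the pool had higher MYC and ribosome biogenesis, heat shock and glycolysis scores. The MYC list correlated with the log10 total count of a line at r = 0.820 (rho 0.764, 0.809 without the 2 farthest lines), heat shock at 0.758 (rho 0.707, 0.741) and glycolysis at 0.730 (rho 0.678, 0.713). G2/M genes followed at 0.644 (rho 0.615, 0.615 without the 2 lines) and S phase genes at 0.609 (rho 0.527, 0.580). Interferon genes went the other way, at -0.372 (rho -0.355, -0.397), as did MHC class I genes at -0.337 (rho -0.353, -0.368) and p53 targets at -0.314 (rho -0.286, -0.323). Each had a permutation p = 1e-05, adjusted p = 1.5e-05 over 18 lists. The plasmablast list (r = -0.0678, rho -0.0622, permutation adjusted p = 0.209) and the immunoglobulin constant list (r = -0.0352, rho -0.0645, adjusted p = 0.492) did not pass. With summed counts as score, however, their r was -0.204 and -0.163, without a permutation test. A different measure, the CPM sum of all genes of a list without TMM scaling, had a rho of -0.273 and -0.224, also without a permutation test. The total of a line depends on its number of cells and on the UMIs per cell, which were not separated. These tests against the line total were not in the plan and were chosen after the scores had been seen, and the same holds for the spreads below.

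Summed levels of the lists differed in width between lines. Immunoglobulin constant genes ran from 5212 CPM at the 5th to 18798 CPM at the 95th percentile with a median of 10422, and MHC class II genes from 2637 to 5682 CPM. Oxidative phosphorylation genes ran from 11425 to 12798 CPM. Between libraries, genes were ranked if they had a mean CPM of at least 10 and the naming rule admits them. Of these, the antiviral gene IFITM1 had the largest coefficient of variation, 41.1%, followed by ARF5 at 25.6%. IFITM1 stood at 16.1, 9.05, 15.1 and 25.5 CPM in replicates 1 to 4.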
